A study of Mus musculus with 6 samples.

How the data were processed

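Total RNA from 6 samples of mouse prostate basal cells, 3 from proximal and 3 from distal ducts, was converted to cDNA with a kit that primes with both random and oligo(dT) primers, made into DNA libraries and sequenced on an Illumina HiSeq, per the labels' protocols. The protocols describe dissociation of the tissue, antibody staining and fluorescence-activated sorting, and also a culture of primary stromal cells. They do not state the antibodies and gates that define the basal cells, whether the basal cells were cultured, or what the replicate numbers stand for. Groups and replicate numbers were taken from the labels.

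Reads were processed with bcl2fastq 1.8.3, TopHat and Cufflinks on the mouse genome build mm10, per the submitters' processing notes, which give no version for TopHat or Cufflinks. Each deposited file lists FPKM (fragments per kilobase of transcript, scaled to the fragments of the library) for 63241 transcripts of 1 library, with an interval and a status for each, per the file headers. Each deposited file also lists the coverage of every transcript, a signal that is not scaled to the depth of the library, per the file headers. Values were used as deposited, with no further scaling between libraries. The annotation's name is not given in the sources used here, and the files hold transcript identifiers and positions without gene names.

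Each transcript was therefore matched to GENCODE M21 (GRCm38, the same assembly as mm10) by its genomic span and its spliced length. A close match needed a product of span overlap and length ratio of at least 0.5, with the best other gene below 0.8 of that score, and gave 49633 transcripts. A further 3718 transcripts were matched because exons of 1 gene within their span amounted to at least 0.8 of their spliced length. Exons of any other gene there could amount to at most 0.1 of it. At least 0.95 of the span had to lie inside the gene, and the length had to be at least 200 bases. The 53351 matched transcripts held 93.9% of the FPKM and gave values for 25272 genes, as the sum of FPKM over the transcripts of a gene. Transcripts matched to no single gene were left out of the main comparison. The matching was tested on 2000 reference transcripts with slightly shifted ends and altered lengths, each removed from the reference before it was matched. Of these, 90.2% were assigned, and 99.9% of those to the right gene. All came from protein-coding genes with more than 1 reference transcript, so these rates do not cover other genes. For 13151 matched protein-coding transcripts with a mean of at least 1 FPKM, the symbol was compared with the best overlapping RefSeq gene. It was that gene's symbol or a synonym of it in 99.7%. Gene positions are those of the annotation on mm10, counted from 1.

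The FPKM values are not counts, and whole fragments could not be recovered from them because Cufflinks divides fragments between transcripts. The depth of each library was instead derived from the width of the deposited intervals of transcripts that overlap no other, and gave 22800000 to 29300000 fragments. At these depths a library's coverage per FPKM differed by at most 1.29-fold from another's. The expression level below which depth limits the comparison was not tested. In 25 transcripts the status was not OK in at least 1 library, and 5 genes held such a transcript. An exact 0 can be a failed estimate, and 141 of the tested genes were listed at 0 in at least 1 library, 11 of them among the called genes. The protocols do not say whether the kit marks strand, so overlapping and antisense genes cannot be told apart with certainty.

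Genes with a mean of at least 1 FPKM over the 6 libraries were tested on log2(FPKM + 1) with limma 3.58.1 (R 4.3.3), using lmFit and eBayes with a trend of variance on level, two-sided, with no covariates, and the Benjamini-Hochberg adjusted p had to be under 0.05. Gene lists for cell identities, pathways and RNA quality were fixed before the data were examined, as were the groups, the main tests, most of the alternative settings and the rule for named genes. Of 41 lists, 39 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Erythroid and neuroendocrine lists had 3 and 0 tested members and were not tested. The named genes are the 10 largest increases and the 10 largest decreases among called genes with a mean of at least 5 FPKM in the higher group and no overlap between the groups, without predicted genes, small RNAs and pseudogenes, up to 4 members with the smallest p of each list that passed and of 8 lists chosen beforehand, and the identity genes Krt5, Krt14, Trp63, Krt8 and Krt18. This gave 101 genes, of which the text names a part, and the results of some genes are not reported here. Genes named in the closing observations outside this rule were chosen after their values were seen.

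The procedure was tested on simulated data, in which 200 of 10264 genes were changed. It recovered 82% of the genes changed by 1 and 95% of those changed by 2 on the log2 scale, all in the right direction, and 2.75% of the calls were false. The genes to be changed were first raised to a set minimum level, so this recovery does not cover genes at a low level. The spread was shuffled between genes and the simulated libraries varied independently. These rates therefore leave out any deviation that real libraries share. No list was called among 39 without a change, in simulated genes that vary independently, so this does not measure false list calls among genes that vary together. Alternatives covered the pseudocount, the filter, the scaling, the limma options, a 1.5-fold null, a replicate block, gene list tests with camera at an estimated correlation and with fry, and leaving out each library in turn. Another 6 alternatives were added after the data had been seen. GC content was taken from the reference transcripts. Figures were drawn with matplotlib 3.10.9 and tables handled with pandas 2.3.3.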

Results

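RNA sequencing was used to compare basal epithelial cells from the proximal and the distal ducts of the mouse prostate. Basal cells line the basement membrane beneath the secretory luminal cells, and the proximal ducts are those nearest the urethra, whereas the distal ducts lie toward the gland tips. The comparison asks how gene expression in basal cells differs between these regions. Each group comprised 3 libraries, prepared from C57BL/6 mice aged 8 to 12 weeks. The depth implied by the deposited intervals was 22800000, 29300000 and 25100000 fragments in the distal libraries and 25700000, 23200000 and 28300000 fragments in the proximal libraries. Between 9918 and 10308 genes reached 1 FPKM in each library. The labels do not say whether the libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical.

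All 6 libraries expressed basal keratins at a high level. Krt14, a basal keratin, reached 2716 ± 597 FPKM in distal and 2186 ± 80.3 FPKM in proximal cells (SD, n = 3), and did not pass the test (limma, adjusted p = 0.365). Krt5, its pairing partner, was higher in proximal cells, at 618 ± 48.9 against 380 ± 50.7 FPKM (SD, n = 3), with a log2 fold change of 0.71 ± 0.13 (SE, limma, adjusted p = 0.0204). Trp63, the transcription factor that defines the basal lineage, lay at 34.2 ± 5.79 FPKM in proximal and 58.5 ± 21.2 FPKM in distal cells (SD, n = 3, limma, adjusted p = 0.170), and was lower in proximal cells on leaving out distal replicate 1 (adjusted p = 0.0112). The luminal keratins Krt8 and Krt18 were also abundant, and neither passed the test (limma, adjusted p = 0.643 and 0.922). Krt18 had a mean of 1279 FPKM in proximal and 1266 FPKM in distal cells, and Krt8 had a mean of 598 FPKM in proximal and 546 FPKM in distal cells. Across genes, the Pearson correlation between libraries was 0.968 to 0.987 within a group and at most 0.971 between groups. Genes are not independent replicates. On principal components, the leading axis held 47.1% of the variance and separated the duct regions, and the next axis held 25.4% and set both libraries numbered 1 apart from the other 4.

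**Figure D1:**
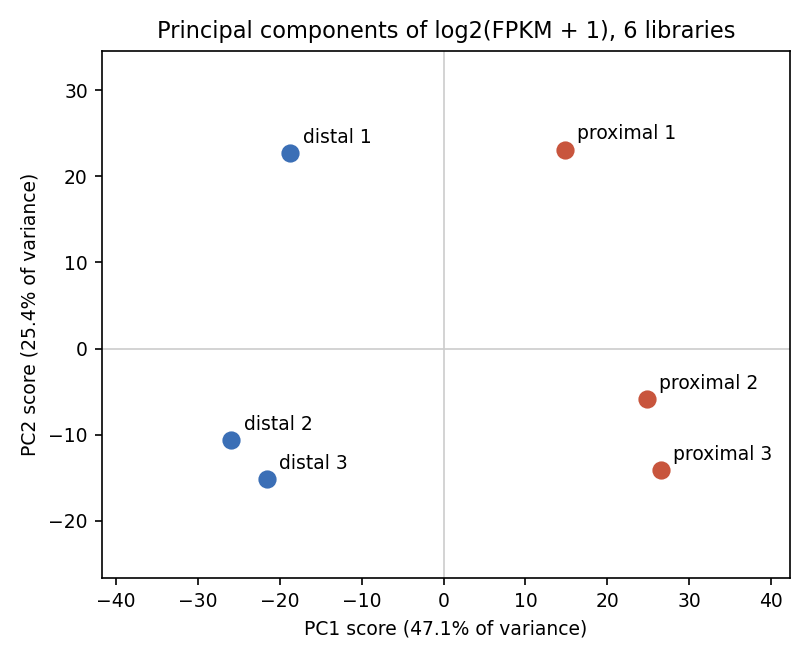
Scores of the 6 libraries on the leading pair of principal components of log2(FPKM + 1) over 10264 genes, with the share of variance on each axis. Proximal libraries (red) have positive and distal libraries (blue) negative PC1 scores, and both libraries numbered 1 lie above 22 on PC2.

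A set of genes stood at a much higher level in the proximal than in the distal libraries. Among them, Psca, Cyp2f2 and Nupr1 belong to the list of proximal luminal progenitor markers. Tspan8 belongs to the luminal markers and Msmb to the prostate secretory products. For these genes, expression by basal cells cannot be told apart from luminal cells carried through the sort. Psca, which encodes a cell surface antigen of the prostate, rose from 0.872 ± 0.516 to 64.1 ± 14.4 FPKM (SD, n = 3), a log2 fold change of 5.13 ± 0.22 (SE, limma, adjusted p = 3.18e-05). Slc14a1, a urea transporter, was at 19.5 ± 2.21 FPKM in proximal against 0.223 ± 0.0394 FPKM in distal cells, and Kcnn4, a calcium-activated potassium channel, at 216 ± 11.1 against 13.4 ± 1.59 FPKM (SD, n = 3). Their log2 fold changes were 4.06 ± 0.13 and 3.92 ± 0.11 (SE, limma, adjusted p = 7.11e-06 and 5.39e-06). Grp, a bombesin-like neuropeptide, Cyp2f2, a cytochrome P450, and Tspan8, a tetraspanin, were higher by 3.84, 3.81 and 3.54 on the log2 scale. Msmb, a protein secreted by the prostate, was listed at 0, 0.108 and 0.122 FPKM in the distal and at 10.4, 8.38 and 9.54 FPKM in the proximal libraries. Slc25a48, a mitochondrial carrier, and Nupr1, a stress-induced nuclear protein, were higher by 3.17 and 3.14 on the log2 scale. Irf5, an interferon regulatory factor, was listed at 0 in all 3 distal libraries and at 9.28, 9.03 and 9.11 FPKM in the proximal libraries. Its span overlaps that of another expressed transcript. Psca lies on chromosome 15 (74714839 to 74717069, mm10), Slc14a1 on chromosome 18 (78100091 to 78142119) and Kcnn4 on chromosome 7 (24370263 to 24386690). The log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of genes at a low level.

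Other genes stood at a higher level in the distal libraries. Areg, which encodes the EGF receptor ligand amphiregulin, was at 211 ± 74.9 FPKM in distal and 50.8 ± 18.5 FPKM in proximal cells (SD, n = 3), a log2 fold change of -2.03 ± 0.29 (SE, limma, adjusted p = 0.00699). Epgn, which encodes a related ligand, epigen, had a log2 fold change of -1.77 ± 0.29 (SE, limma, adjusted p = 0.0119). Defb50, a beta-defensin, was at 1344 ± 235 FPKM in distal and 327 ± 103 FPKM in proximal cells, Scpep1, a serine carboxypeptidase, at 1589 ± 116 and 459 ± 97.8 FPKM, and Cpe, the prohormone-processing carboxypeptidase E, at 223 ± 17.0 and 62.9 ± 5.20 FPKM (SD, n = 3). Defb50 belongs to the list of prostate secretory products. Of its 12 tested members 1 was higher, 2 were lower and 9 did not pass, and the list did not pass (camera, adjusted p = 0.955). Whether Defb50 transcripts came from basal cells or from secretory cells carried through the sort was not tested. Elobl, an elongin B-like gene, had the lowest log2 fold change among the named genes, -2.96 ± 0.20 (SE, limma, adjusted p = 0.000244). Ren1, which encodes renin, and Pnliprp1, a pancreatic lipase-related gene, had log2 fold changes of -1.83 and -1.75. The call of Epgn was lost on leaving out distal replicate 2 or proximal replicate 2, with adjusted p-values up to 0.0579. Htra2, a mitochondrial protease, was listed at 5.41, 6.11 and 4.16 FPKM in distal libraries and at 0 in all 3 proximal libraries, and its span too overlaps that of another expressed transcript. Elobl lies on chromosome 11 (88964658 to 88966931, mm10), Areg on chromosome 5 (91139599 to 91148432) and Defb50 on chromosome 8 (21823539 to 21831296).

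**Figure D2:**
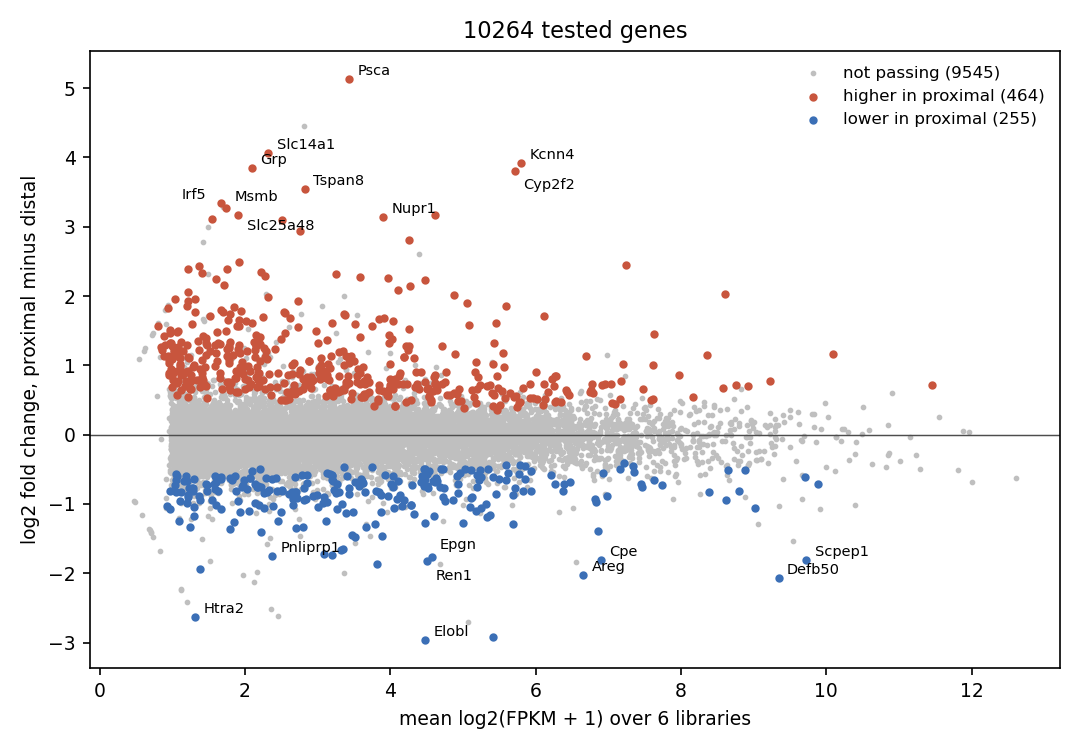
Log2 fold change (proximal minus distal) against mean log2(FPKM + 1) over the 6 libraries for 10264 tested genes. Red points are the 464 genes higher and blue points the 255 genes lower in proximal cells at an adjusted p under 0.05, and 19 of the named genes with the largest changes carry their symbols.

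In all, 464 of 10264 tested genes were higher and 255 were lower in proximal basal cells (limma, adjusted p under 0.05), which is 7.01% of the genes tested. Of these, 189 higher and 65 lower genes changed more than 2-fold on the FPKM + 1 scale. This leaves out called genes at a low level whose FPKM changed more than 2-fold, such as Pdgfrb. The groups' values did not overlap for any of the 719 called genes. They also did not overlap for 28.8% of all tested genes, where chance gives 10%. The counts depended on which libraries entered the test. Leaving out 1 library gave 516 higher and 622 lower genes without distal replicate 1, 534 and 549 without proximal replicate 1, 205 and 46 without distal replicate 2, 240 and 61 without distal replicate 3, 202 and 53 without proximal replicate 2, and 255 and 73 without proximal replicate 3. Without both libraries numbered 1, 908 genes were higher and 1385 lower, among them 442 of the 464 and 253 of the 255. With no expression filter 18576 genes were tested, and the calls of Krt5, Axin2, Apcdd1, Bambi, Id3, Emcn, Eng, Junb, Cdkn2d, Hoxb13, Flna, Itgb6, Pmepa1, Wnt10a, Rpl13, Rps16, Hist1h4m and Hist1h4i ended, with adjusted p-values from 0.0532 to 0.105.

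Markers of proximal luminal progenitor cells formed the list with the clearest rise. Of its 16 tested members, 11 were higher, none was lower and 5 did not pass, and 14 were higher when adjusted over the list alone. Besides Psca, Cyp2f2 and Nupr1, the members that rose included Krt7, a keratin of simple epithelia, from 64.8 ± 11.7 to 355 ± 31.0 FPKM (SD, n = 3, log2 fold change 2.45 ± 0.15 SE), and Krt4, a keratin of stratified mucosa, from 1.46 ± 0.236 to 18.2 ± 4.79 FPKM (log2 fold change 2.94 ± 0.19 SE). The list had a median log2 fold change of 1.35 and passed the competitive test (camera, adjusted p = 5.18e-13). Its adjusted p = 0.298 with an estimated correlation. Of the 14 tested general luminal markers, 3 were higher, 2 were lower and 9 did not pass. Krt19 rose from 193 ± 21.6 to 787 ± 28.4 FPKM (SD, n = 3), with a log2 fold change of 2.03, and the tight junction gene Cldn3 had a log2 fold change of 1.11. Tspan8 was the other higher member, and the lower members included Hoxb13, a homeobox transcription factor. The call of Hoxb13 was lost on leaving out distal replicate 2 or 3 or proximal replicate 2 or 3, with adjusted p-values up to 0.102. Over the list alone 4 members were higher and 3 lower, and the list as a whole did not pass (camera, adjusted p = 0.179). With closely matched transcripts only, the luminal list did pass as higher.

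**Figure D3:**
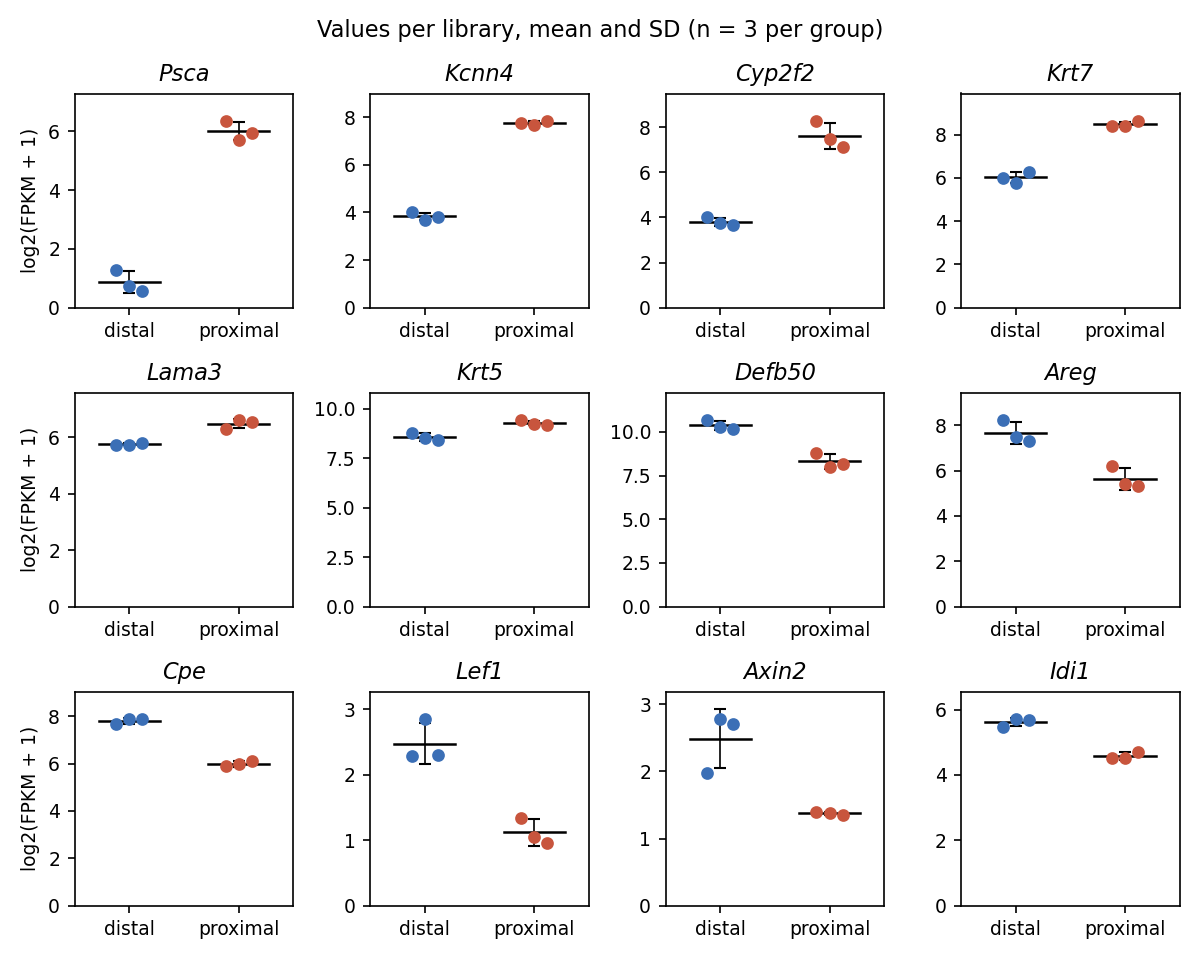
Values of 12 named genes in each library as log2(FPKM + 1), with the mean (horizontal bar) and SD (error bar) of the 3 distal (blue) and 3 proximal (red) libraries. The groups do not overlap for any of these genes, and Psca shows the widest gap, from 0.872 FPKM in distal to 64.1 FPKM in proximal cells.

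Genes of the basement membrane and its integrin receptors were higher in proximal cells. Of 27 tested members, 12 were higher, none was lower and 15 did not pass, and over the list alone 16 were higher and 1 was lower. Col4a1, a type IV collagen chain, rose from 32.7 ± 1.72 to 66.1 ± 12.4 FPKM, Itgav, the integrin alpha V subunit, from 83.8 ± 4.00 to 141 ± 12.8 FPKM, and Lama3, a laminin chain, from 52.9 ± 1.44 to 88.9 ± 9.90 FPKM (SD, n = 3). Nid2, which encodes the linker protein nidogen 2, was listed at 0.362, 0 and 0.448 FPKM in the distal and at 1.93, 2.56 and 1.94 FPKM in the proximal libraries. The list had a median log2 fold change of 0.45 (camera, adjusted p = 1.32e-08, and adjusted p = 0.426 with an estimated correlation), with a mean deviation of 0.07 in proximal replicate 1 against 0.32 and 0.28 in proximal replicates 2 and 3. Endothelial, fibroblast and nerve and glia markers, of cell types that also make basement membrane proteins such as Col4a1 and Nid2, were higher in the proximal libraries too, with median log2 fold changes of 1.09, 0.64 and 0.74. The list of basal epithelial markers, which shares Lama3 and Lamb3 with it, had 6 higher, 0 lower and 11 members that did not pass, with 8 higher and 1 lower over the list alone. Among its higher members were Lama3, Krt5 and Lamb3, with log2 fold changes of 0.73, 0.71 and 0.45. The basal list passed narrowly (camera, adjusted p = 0.0428, and adjusted p = 0.426 with an estimated correlation). Its call was lost on leaving out distal replicate 1 or 3 or proximal replicate 2 or 3, with adjusted p-values up to 0.123, and also under median ratio, quantile or rescaled values, with a filter at 5 FPKM, without the variance trend and with the length trend removed (adjusted p from 0.0513 to 0.0727). The calls of Krt5 and Lamb3 were lost on leaving out distal replicate 2 or 3 or proximal replicate 2 or 3, with adjusted p-values up to 0.104 and 0.126.

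Target genes of Wnt/beta-catenin signaling were lower in proximal cells. All 13 tested members had a negative log2 fold change, of which 5 were lower by the test and 8 did not pass, and 9 were lower over the list alone. Lef1, a transcription factor that binds beta-catenin, was at 1.18 ± 0.316 FPKM in proximal against 4.66 ± 1.32 FPKM in distal cells (SD, n = 3), a log2 fold change of -1.36 ± 0.20 (SE, limma, adjusted p = 0.00701). Axin2, a feedback inhibitor of the pathway, was at 1.60 ± 0.0391 against 4.78 ± 1.59 FPKM, and Nkd1, another feedback inhibitor, at 1.12 ± 0.188 against 3.09 ± 0.535 FPKM (SD, n = 3). Apcdd1, an inhibitor at the cell surface, had a log2 fold change of -0.83. The calls of Axin2 and Apcdd1 were lost on leaving out distal replicate 2 or 3 or proximal replicate 2 or 3, with adjusted p-values up to 0.0973 and 0.136, and that of Nkd1 without distal replicate 2 or 3 or proximal replicate 3, up to 0.0611. The list had a median log2 fold change of -0.67 (camera, adjusted p = 6.65e-06, and adjusted p = 0.426 with an estimated correlation), and its mean deviation was 0.10 in distal replicate 1 against 0.42 and 0.46 in distal replicates 2 and 3, beside -0.15, 0.65 and 0.66 for dissociation and immediate early genes in the same libraries. Wnt ligands, receptors and secreted modulators went both ways, with 5 of 25 higher, 1 lower and 19 not passing, and 6 higher and 3 lower over the list alone. Wnt7b, a ligand, rose from 11.5 ± 1.25 to 26.2 ± 3.91 FPKM, and Sfrp1, a secreted Wnt inhibitor, from 0.979 ± 0.0622 to 4.80 ± 1.96 FPKM (SD, n = 3). Sfrp5, of the same inhibitor family, and Wnt10a, a ligand, had log2 fold changes of 1.33 and 0.81, and their calls were lost without distal replicate 3, with adjusted p-values up to 0.0573 and 0.0753, that of Wnt10a also without proximal replicate 2 or 3. The ligand list as a whole did not pass (camera, adjusted p = 0.270).

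BMP target genes were lower in proximal cells, with 2 of 9 members lower and 7 not passing, and 3 lower over the list alone (camera, adjusted p = 0.0338, and adjusted p = 0.426 with an estimated correlation). The lower members were Id3, an inhibitor of helix-loop-helix transcription factors, at 369 ± 118 against 758 ± 142 FPKM (SD, n = 3), and Bambi, a decoy receptor, with a log2 fold change of -0.70. Proximal replicate 1 lay nearer the distal libraries, with a mean deviation of 0.02 against -0.26 and -0.30 in proximal replicates 2 and 3, and Id3 was at 505 FPKM there against 288 and 316 FPKM. The list's call was lost without proximal replicate 3, with an adjusted p of 0.0597, and those of Id3 and Bambi on leaving out distal replicate 2 or 3 or proximal replicate 2 or 3 (Id3 also distal replicate 1), with adjusted p-values up to 0.135 and 0.128. TGF-beta target genes did not pass as a list (camera, adjusted p = 0.516), with 3 of 19 higher, 1 lower and 15 not passing, and 4 higher and 2 lower over the list alone. The higher members were Col4a1, Itgb6, an integrin subunit that takes part in TGF-beta activation, and Pmepa1, a feedback inhibitor, and the lower member was Bambi. The log2 fold changes of Itgb6 and Pmepa1 were 0.84 and 0.51, and both calls were lost on leaving out distal replicate 2 or 3 or proximal replicate 2 or 3, that of Itgb6 also without distal replicate 1 and that of Pmepa1 without proximal replicate 1, with adjusted p-values up to 0.163 and 0.171.

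Genes of cholesterol and fatty acid synthesis were lower in proximal cells, with 6 of 20 members lower, none higher and 14 not passing, and 9 lower over the list alone. Idi1 and Cyp51, which encode enzymes of the sterol pathway, were at 22.9 ± 1.95 and 23.6 ± 1.64 FPKM in proximal against 48.4 ± 4.24 and 52.3 ± 6.99 FPKM in distal cells (SD, n = 3). Insig1, which restrains sterol synthesis and is itself a target of the sterol response, was at 12.6 ± 1.21 against 29.3 ± 4.39 FPKM (SD, n = 3). The list had a median log2 fold change of -0.46 (camera, adjusted p = 8.32e-06, and adjusted p = 0.426 with an estimated correlation), with a mean deviation of 0.03 in distal replicate 1 against 0.29 and 0.32 in distal replicates 2 and 3, where the dissociation and immediate early genes also stood higher than in distal replicate 1 (0.65 and 0.66 against -0.15). In the proliferation list 1 of 11 tested members was lower and 10 did not pass (camera, adjusted p = 0.181). With no expression filter, which adds members at a low level, the proliferation list passed as lower (camera, adjusted p = 0.00485). The lower member in the main test, also over the list alone, was Rrm2, a subunit of ribonucleotide reductase, with a log2 fold change of -0.87, and its call was lost without distal replicate 2 or 3, with an adjusted p up to 0.0632. Cell cycle inhibitors passed as a lower list (camera, adjusted p = 0.0412, and adjusted p = 0.463 with an estimated correlation), with 1 of 13 higher, 1 lower and 11 not passing, and 1 higher and 3 lower over the list alone. Its mean deviation was -0.03 in distal replicate 1 against 0.25 and 0.30 in distal replicates 2 and 3. In the latter the dissociation genes stood higher too, but Btg2 belongs to both lists, at 281, 497 and 497 FPKM in distal replicates 1 to 3. The lower member of the cell cycle inhibitor list was Cdkn2d and the higher member Cdkn1c, both inhibitors of cyclin-dependent kinases. Their log2 fold changes were -1.10 and 0.83. Both calls, and the list's, were lost without proximal replicate 2, with adjusted p-values up to 0.0954, 0.0598 and 0.0822 over the omissions. The call of Cdkn2d was also lost without distal replicate 2 or 3, that of Cdkn1c without distal replicate 2 and the list's without distal replicate 3, under quantile normalization (adjusted p = 0.0551) and with a filter at 5 FPKM (adjusted p = 0.118).

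Interferon-stimulated genes were higher in proximal cells, with 6 of 18 members higher, none lower and 12 not passing, and 8 higher and 2 lower over the list alone. Gbp2, a guanylate-binding protein, rose from 1.85 ± 0.0436 to 6.56 ± 0.859 FPKM, and Ifit1 and Rsad2, antiviral effectors, rose from 1.23 ± 0.175 to 4.33 ± 0.735 FPKM and from 0.452 ± 0.106 to 2.15 ± 0.0659 FPKM (SD, n = 3). The list had a median log2 fold change of 0.36 (camera, adjusted p = 0.000860, and adjusted p = 0.426 with an estimated correlation), and its call was lost with a filter at 5 FPKM (adjusted p = 0.207). Xenobiotic and antioxidant genes were also higher as a list, with 5 of 18 members higher, 1 lower and 12 not passing, and 7 higher and 1 lower over the list alone (camera, adjusted p = 0.00269, and adjusted p = 0.463 with an estimated correlation). The median log2 fold change was 0.20 and the mean 0.58, and Cyp2f2 is shared with the proximal luminal progenitor list. Its mean deviation as a list was 0.46 in proximal replicate 1 against 0.17 and 0.23 in proximal replicates 2 and 3. In distal replicate 1 it was -0.14, against -0.35 and -0.38 in distal replicates 2 and 3. Gsta4, a glutathione transferase, rose from 9.39 ± 1.37 to 47.8 ± 6.10 FPKM (SD, n = 3). Gpx2, a glutathione peroxidase, had a log2 fold change of 1.41, and its call was lost without distal replicate 2 or proximal replicate 2, with an adjusted p up to 0.0569.

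**Figure D4:**
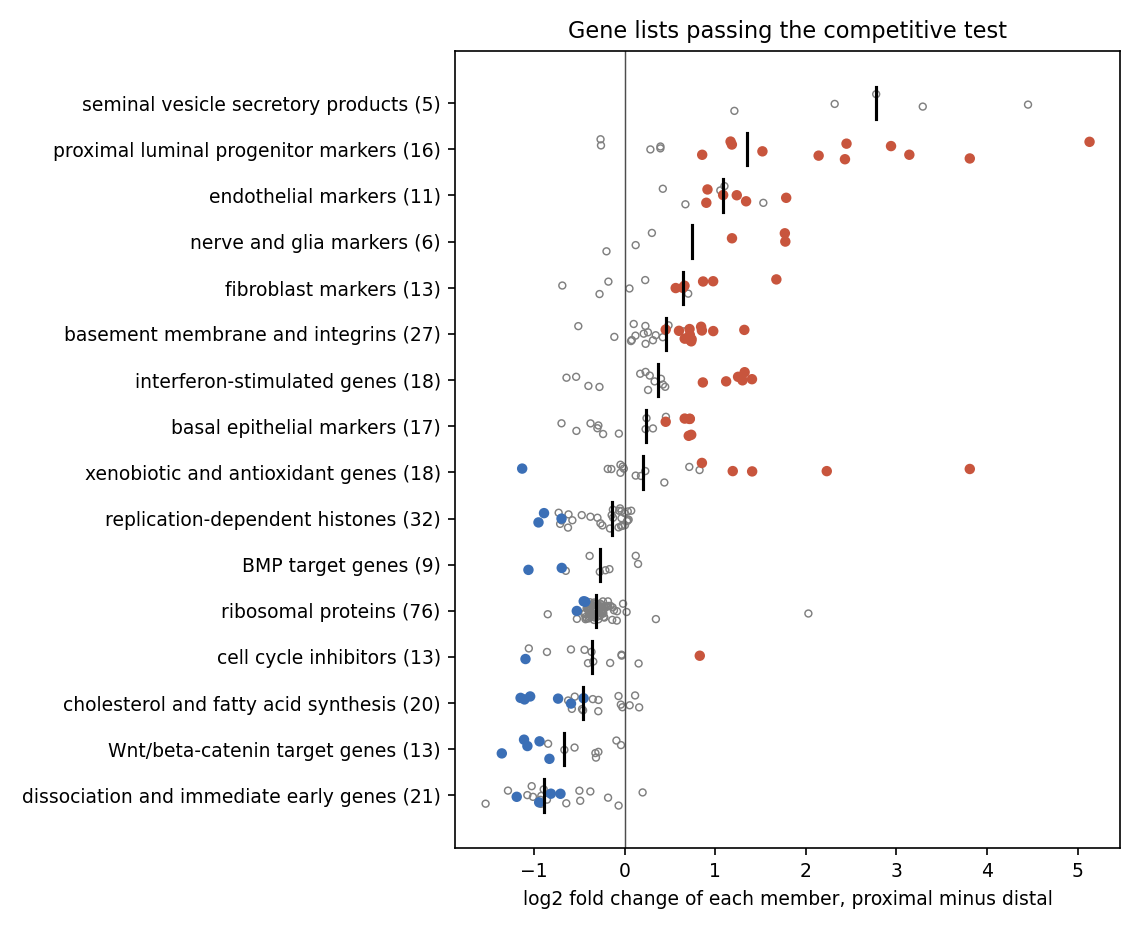
Log2 fold change (proximal minus distal) of every tested member of the 16 gene lists that passed the competitive test, with the number of members in parentheses. Filled points passed the test for single genes (red higher, blue lower), open points did not, black bars are medians, and vertical scatter is for display. Medians run from -0.90 for dissociation and immediate early genes to 2.78 for the seminal vesicle list, none of whose members passed.

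Markers of several other cell types were higher in the proximal libraries as well. All 11 tested endothelial markers had a positive log2 fold change, 6 of them were higher by the test, and 11 were higher over the list alone. Emcn, which encodes endomucin, and Eng, which encodes endoglin, were at 6.13 ± 0.276 and 4.29 ± 1.21 FPKM in proximal against 1.32 ± 1.39 and 1.26 ± 0.640 FPKM in distal cells (SD, n = 3). Both calls were lost without distal replicate 2 or 3 or proximal replicate 2, and that of Emcn also without proximal replicate 3, with adjusted p-values up to 0.106 and 0.110. The list passed (camera, adjusted p = 2.61e-07, and adjusted p = 0.426 with an estimated correlation). Distal replicate 1 lay nearer the proximal libraries than the other distal libraries did, with a mean deviation of -0.06 against -0.97 and -0.62, and Emcn was at 2.89 FPKM there against 0.264 and 0.806 FPKM. Among 6 nerve and glia markers 3 were higher, also over the list alone. Among them was Cdh19, which encodes a cadherin of glial cells, at 2.12 ± 0.252 FPKM in proximal against 0.371 ± 0.0810 FPKM in distal cells (SD, n = 3). The list had an adjusted p of 0.00278 by camera, and adjusted p = 0.426 with an estimated correlation. Among 13 fibroblast markers 6 were higher, none was lower and 7 did not pass, with 8 higher and 2 lower over the list alone (camera, adjusted p = 0.00204, and adjusted p = 0.426 with an estimated correlation), and the call was lost without the expression filter (adjusted p = 0.0656). Vim, which encodes vimentin, rose from 7.11 ± 1.37 to 24.7 ± 2.29 FPKM and Col3a1, a fibrillar collagen, from 7.83 ± 1.33 to 16.3 ± 1.67 FPKM (SD, n = 3). Smooth muscle markers did not pass as a list (camera, adjusted p = 0.205), with Flna, which encodes the actin crosslinker filamin A, the 1 higher member of 10, also over the list alone. Its log2 fold change was 0.49, and its call was lost on leaving out distal replicate 2 or 3 or proximal replicate 2 or 3, with adjusted p-values up to 0.148. Immune cell markers did not pass either (camera, adjusted p = 0.699), with 1 of 7 higher. Secretory genes of the seminal vesicle passed as a list of 5 (camera, adjusted p = 0.0412, and adjusted p = 0.463 with an estimated correlation) without a single member passing. Svs5 was at 0.391, 107 and 239 FPKM in the proximal libraries and at 0.325, 0.860 and 0.393 FPKM in the distal libraries, so the difference rests on proximal replicates 2 and 3. The seminal vesicle list's call was lost without distal replicate 1 or 3, with an adjusted p up to 0.0906, and with a pseudocount of 5, quantile or rescaled values, fry and voom, up to 0.291 with voom, and without proximal replicate 2 or 3 fewer than 5 of its members could be tested.

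**Figure D5:**
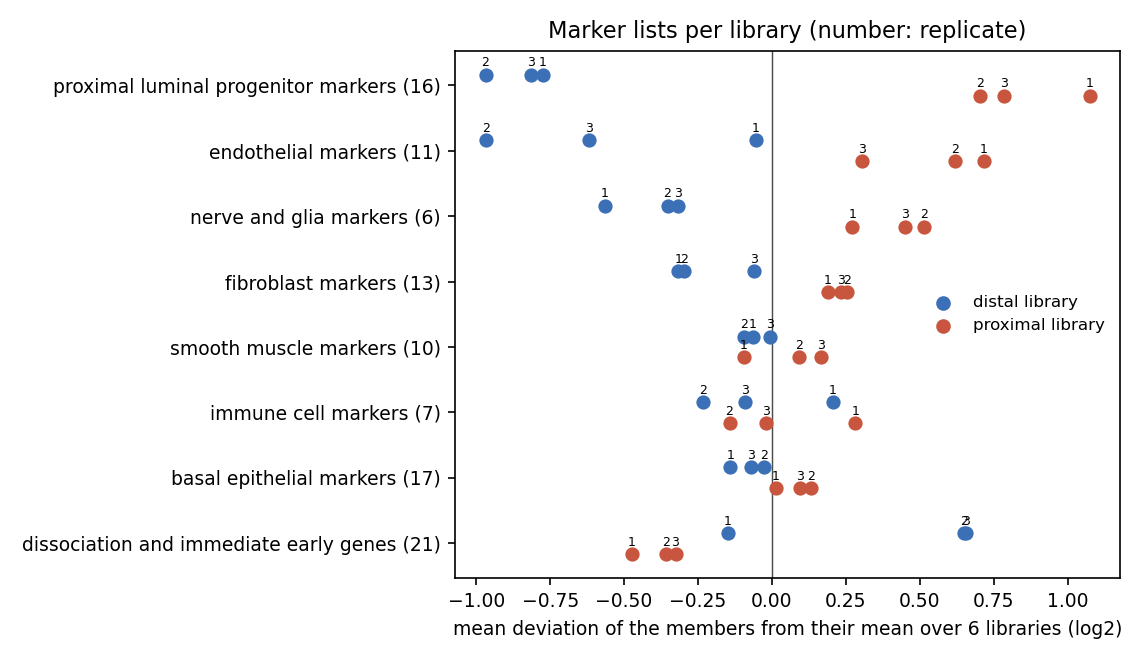
Mean deviation of the members of 8 gene lists from their mean over the 6 libraries, on the log2 scale, for each distal (blue) and proximal (red) library, with replicate numbers above the points and the number of members in parentheses. The proximal luminal progenitor list separates the groups, from -0.97 to -0.78 in distal and from 0.70 to 1.07 in proximal libraries, whereas the immune list overlaps.

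Genes that respond to tissue dissociation were lower in the proximal libraries, with 4 of 21 members lower, none higher and 17 not passing, and 13 lower over the list alone. Ier2 and Junb, immediate early genes, were at 283 ± 19.8 and 739 ± 70.2 FPKM in proximal against 551 ± 87.0 and 1213 ± 157 FPKM in distal cells (SD, n = 3). The call of Junb was lost on leaving out distal replicate 2 or 3 or proximal replicate 2 or 3, with adjusted p-values up to 0.136. The list passed (camera, adjusted p = 1.82e-07, and adjusted p = 0.426 with an estimated correlation), and its mean deviation was -0.15 in distal replicate 1 against 0.65 and 0.66 in distal replicates 2 and 3. Of 76 ribosomal protein genes, 73 had a negative log2 fold change, with a median of -0.32, and 3 were lower by the test, among them Rpl23a with a log2 fold change of -0.53 (the others were Rpl13 and Rps16), while 30 were lower over the list alone (camera, adjusted p = 5.18e-13, and adjusted p = 0.463 with an estimated correlation). The ribosomal list's mean deviation was 0.29 in distal replicate 1 and -0.32 in proximal replicate 2, against 0.09 and 0.03 in the other distal and -0.04 and -0.06 in the other proximal libraries. The call of Rpl23a was lost on leaving out distal replicate 2 or 3 or proximal replicate 2 or 3, with adjusted p-values up to 0.118, and those of Rpl13 and Rps16 also without distal replicate 1, up to 0.161 and 0.180. Of 32 replication-dependent histone genes, 3 were lower, 29 did not pass and 8 were lower over the list alone, with a median log2 fold change of -0.14 (camera, adjusted p = 0.00310, and adjusted p = 0.429 with an estimated correlation). The lower members were the near-identical H4 genes Hist1h4n, Hist1h4m and Hist1h4i, between which reads can be shared. Their calls were lost on leaving out distal replicate 2 or 3 or proximal replicate 3, with adjusted p-values up to 0.139, those of Hist1h4m and Hist1h4i also without proximal replicate 1 and those of Hist1h4n and Hist1h4i without proximal replicate 2. The histone list's call ended when the trend on transcript length was removed (adjusted p = 0.124). Altogether 9 of the 39 tested lists passed as higher and 7 as lower, and by camera none passed with an estimated correlation, where 3 had an unadjusted p under 0.05. By fry, which tests whether the members move on balance in a single direction, 11 lists passed, of which 9 are among the 16 that passed camera. The other lists that passed fry are the luminal markers (adjusted p = 0.00418) and the squamous and keratinization genes (adjusted p = 0.0208). By fry the calls were lost for endothelial markers (adjusted p = 0.0606), dissociation genes (adjusted p = 0.0690), BMP targets (adjusted p = 0.0893), ribosomal proteins (adjusted p = 0.0909), histones (adjusted p = 0.0961), cell cycle inhibitors (adjusted p = 0.125) and the seminal vesicle list (adjusted p = 0.202).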

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

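The tests of other cell types and of depth were chosen after the results were seen. Of the transcripts matched to no single gene, 430 were tested, and 9 were higher and 13 were lower in proximal cells, a signal in data that the comparison of genes leaves out. The transcript at chromosome 11, 88970942 to 88973031 (mm10), was at 111, 184 and 167 FPKM in distal and at 12.4, 11.5 and 22.5 FPKM in proximal libraries. Its log2 fold change was -3.27 ± 0.27 (SE, limma, adjusted p = 0.000823), and it was chosen after its values were seen. This transcript lies within the span of Coil, a gene that is itself called lower (log2 fold change -1.73) and follows the lower gene Elobl. It is therefore not a signal at a locus apart from the called genes.

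Irf5, Htra2 and 22 other tested genes were listed at 0 in all 3 libraries of a group, 11 genes in distal and 13 in proximal libraries. Irf5 and Mrrf were called higher and Htra2 lower. The span of 75% of these 24 genes overlaps that of another transcript with a mean of at least 1 FPKM, against 7.74% of 6809 other genes in the same range of expression (exact Fisher p = 1.12e-15). The zeros may therefore come from the way fragments are divided between overlapping transcripts, and a difference between the duct regions in these 3 called genes stays open, as it was not tested apart from the overlap.

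Endothelial and proximal luminal markers were higher in proximal libraries. A smaller share of basal cells would raise the markers of every other cell type alike only if those cells were mixed alike in both duct regions. Over the 5 lists of other types the log2 fold changes differed (38 members under 10 FPKM in distal cells, Kruskal-Wallis permutation p = 7e-04 over genes, which are not independent replicates). The medians were 1.09 for endothelial, 0.66 for fibroblast, 1.18 for nerve and glia, 0.12 for smooth muscle and -0.04 for immune markers, a range of 1.22. The limit was set on distal cells alone, and tested genes needed a mean of at least 1 FPKM, so it favours members higher in proximal cells. With all tested members the medians were 1.09, 0.64, 0.74, 0.10 and -0.05 in the same order. On the log2(FPKM + 1) scale an equal fold rise also gives unequal values at different low levels. The mix of cells in each region is not known, so these differences cannot decide whether the share of basal cells was smaller. Endothelial cells carried through the sort are a candidate source for their own markers (Emcn, Pecam1 and Plvap at 6.13, 6.09 and 6.04 FPKM in proximal cells): within groups these varied together with a mean correlation of 0.751, above all 10000 random lists of like expression (95th percentile 0.265), which is not specific to carried cells, since hypoxia and glycolysis genes had 0.906 and ribosomal proteins 0.670, and a gate against endothelial cells is not stated. For proximal luminal cells the measure was 0.114, at percentile 84.7 of random lists (95th percentile 0.191), which decides neither way, so luminal cells carried through the sort cannot be told apart from expression by basal cells. In that list 5 of 16 genes stand in another list too, and Cldn4 and Gsto1 were at 2123 and 734 FPKM in distal cells.

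Both libraries numbered 1 deviated alike from their groups, with a correlation of 0.383 across genes. Depth is argued against, since the proximal library numbered 1 differed from the mean of its group's others by -0.376% and the distal by -16.1%. The correlation was 0.362 (bootstrap SE 0.0273) after the trend on transcript length was removed from each library and 0.383 (SE 0.0296) after that on GC content, so neither trend accounts for it as a whole. A difference in preparation or between animals is a possible explanation that stays open, because the labels do not say what the numbers stand for.

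There are 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05. A split and its mirror image are the same, so for every other split the larger count of either direction was taken. For genes higher, 1 split, the real one, reached 464, and the highest other count was 7. For genes lower, 1 split reached 255, against the same highest other count of 7 in either direction. For lists higher, 1 split reached 9 and the highest other count was 8, and for lists lower 3 splits reached 7 or more, with 8 as the highest other count.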

How the results depend on the processing

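Alternatives without both libraries numbered 1, with closely matched transcripts, without genes at 0, with protein-coding genes, with the length trend removed and with voom were chosen after the data were seen. Higher and lower genes numbered 464 and 255. Lower genes were 137 without a filter and 383 after quantile normalization; a filter at 5 FPKM, which tests fewer genes, gave 273 higher and 168 lower genes and 4 higher lists. Sample weights gave 1354 and 1859, the 2 against 2 comparison 908 and 1385, and a test against a 1.5-fold change, stricter by construction, 72 and 10. Leaving out each library gave 202 to 534 higher and 46 to 622 lower genes. A replicate block gave 880 higher and 730 lower genes, with 464 and 254 of the called genes among them; deviations of libraries with the same number correlated by 0.383, 0.0400 and 0.282, and distal replicate 2 did not correlate best with its own number. Camera with an estimated correlation called 0 higher and 0 lower lists (3 at an unadjusted p under 0.05), and fry 9 higher and 2 lower lists. Over all settings, gene results kept direction and side of the threshold in 2177 cases, lost the call in 245 and gained it in 46. Krt18, not called, had a log2 fold change of 0.04, from -0.062 (without distal replicate 2) to 0.24 (without distal replicate 1), and was also negative without distal replicate 3 (-0.05) and proximal replicate 1 (-0.01). All 16 lists that passed kept their direction in every setting that tested them. Apart from smaller tested sets or stricter nulls, the cause was not tested. The expression level at which depth limits the calls was not tested either. edgeR and DESeq2 were not run because whole reads are not recoverable from FPKM. The voom setting used approximate counts, rebuilt from FPKM, the implied depth and the length of each gene's most expressed transcript.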

Other observations

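The test of neighbouring genes was chosen after the result was seen, as were the genes named in this part. Among 20 tested squamous and keratinization genes 3 were higher, 4 were lower and 13 did not pass, with 4 higher and 6 lower over the list alone (camera, adjusted p = 0.585). Krt13, Krt6a and Krt6b, keratins of stratified and stressed epithelia, had log2 fold changes of 2.08, 1.86 and 1.55. Of 17 FGF and EGF ligands and receptors 2 were higher, 3 were lower and 12 did not pass, with 3 higher and 3 lower over the list alone (camera, adjusted p = 0.607). Ereg, which encodes the EGF receptor ligand epiregulin, had a log2 fold change of -0.81, beside -2.03 for Areg.

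Of 10 Notch pathway genes none passed (camera, adjusted p = 0.0731), and the unfolded protein response list, which leaned lower with a median log2 fold change of -0.20 and 15 of 20 members negative, did not pass either (camera, adjusted p = 0.0817). Of its members 1 was higher and 19 did not pass. This list passed as lower in 5 other settings (camera, lowest adjusted p = 0.00253). These were sample weights, the replicate block, the 2 against 2 comparison, and leaving out distal replicate 2 or proximal replicate 1. The Notch list passed as lower in 3 (camera, lowest adjusted p = 0.0376), with the replicate block and without distal replicate 3 or proximal replicate 2. Hypoxia and glycolysis genes deviated by -0.46 in distal replicate 1 and -0.58 in proximal replicate 1 on the log2 scale, against 0.06 to 0.41 in the other libraries (camera, adjusted p = 0.342). That list passed as lower without distal replicate 1 and without proximal replicate 3 (camera, lowest adjusted p = 0.0099). The ribosomal list had a median log2 fold change of -0.32, and -0.24 after the trend on transcript length was removed (camera, adjusted p = 7.56e-10).

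Called genes of the same direction may lie next to each other along the chromosomes. Of 6599 neighbouring pairs of tested genes within 100 kb, 38 were both called in the same direction, against a mean of 17.5 and a highest count of 35 in 10000 random placements (permutation p = 1e-04, the smallest these can give). Of the pairs, 25 were higher and 13 lower, and 18 shared the start of their symbols, as members of a family do. The random placements took no account of families or of expression level, so an excess beyond such families was not tested. On chromosome 11, Akap1, Scpep1, Elobl and Coil lie in a row from 88830792 to 88991613 (mm10), with log2 fold changes of -1.01, -1.81, -2.96 and -1.73. On chromosome 5, Epgn, Ereg and Areg, genes of EGF receptor ligands, lie in a row, and on chromosome 8 Defb1, Defb50 and Defb2, beta-defensin genes, with log2 fold changes of -0.92, -2.07 and -1.29. Whether shared regulation or transcription that runs on into the next gene accounts for such pairs was not tested.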
